A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

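The data are 3 two-colour Agilent tiling arrays of Schizosaccharomyces pombe, 1 per group. Per the labels' protocols, cells were fixed with paraformaldehyde at 18 °C for 30 min and with dimethyl adipimidate for 45 min, sheared by sonication and precipitated with an antibody against GFP. ChIP and input DNA were amplified by random-primed PCR, and the ChIP DNA was coupled to Cy5 and the input to Cy3, with no dye swap among the arrays. Groups and dyes were taken from the labels.

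Per the file headers, the scanner images were read with Agilent Feature Extraction 11.0.1.1 for wild type and 11.5.1.1 for clr4d and cdc10-v50. The processed intensity of each channel in the deposited files is background-subtracted, spatially detrended and dye-normalized by that software, with linear dye factors recorded in the headers, and a multiplicative detrending fit that is 0 on the clr4d array. The deposited files also hold median and local background intensity, which are not normalized, a log10 ratio of red over green, and 0 or 1 flags for saturation, signal above background and non-uniform spots. The authors' value table of the series holds log2 of green over red, opposite in sign to the ChIP over input ratios given here. It equals minus the scanner ratio to within 0.001 on all 41551 probes of wild type and of clr4d and on 41513 of cdc10-v50. Its columns have medians of -0.17, 0.04 and 0.06 and are not centred, so scale, centring and direction are all known. The table served as an alternative source of values.

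From these files the log2 ratio of red over green processed signal was computed per probe and centred on the median over all genome probes of its array, with no loess or quantile step, since most probes of a ChIP array carry signal. The medians before centring were 0.17, -0.04 and -0.06. The 1417 control spots were left out, as were spots marked non-uniform in either channel: 62 in wild type, 9 in clr4d and 1215 in cdc10-v50. The 4 probes of the clr4 deletion were left out of the clr4d values. Saturated probes were kept. At a probe saturated in the ChIP channel of wild type the ratio there is a lower bound, so folds of wild type over a mutant are given as minimum values at such probes, and rises over wild type as upper limits with no fold. Probes not well above background numbered 3, 1 and 79. The software's quality summary marked the cdc10-v50 array for evaluation and the others as in range. The number of arrays, 1 per group, limits the precision of every value. The median signals were 19298 green and 20401 red in wild type, 9869 and 8944 in clr4d, and 9740 and 8436 in cdc10-v50, and the SD of the log2 ratio among arm probes was 0.64, 0.67 and 0.60.

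The genome build of the array is not given in the sources used here. Tile positions were compared with the reference assembly ASM294v3 by correlating the input signal with GC content of the 300-bp window at shifts in both directions, per 100-kb stretch. On the left arm of chromosome III 10 stretches fitted best at shifts from -100 to 80 bp. Elsewhere 114 of 116 stretches fitted best more than 500 bp away, and the largest shift was 4540 bp. Positions are therefore the array's own, counted from 1, and the reference served for gene names, neighbours and orientation between 50 and 1000 kb of chromosome III alone. There, 374 protein-coding genes lay on the stretch and 337 had at least 3 probe centres inside. Centromeres were the longest intervals between adjacent protein-coding genes, with 5 kb taken off on either side because positions are uncertain. Subtelomeres were the outer 50 kb of chromosomes I and II on the array. The arms held 39804 probes. Names of 1727 probes end in f, m or r; the meaning of these marks is not given in the sources used here, and they are concentrated in repeated regions.

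A region's value is the median over probes. A gene's value is the mean over its probes. Values of 2-kb windows at the centromeres and of 5-kb steps from the chromosome ends are also means over probes. Peaks are stretches of at least 3 probes whose running mean over 3 probes is at least 1, joined within 1 kb, compared by an overlap of 1 bp or more with 1000 random placements. Medians of each channel alone were centred on the arm median of that channel. Named genes were the 10 largest rises and 10 largest falls of each mutant against wild type, and 5 each way between the mutants, among genes with every probe above background and changed the same way, at most 1 per 10 kb, plus the label check, the 10 highest wild-type arm peaks and members of the gene lists. The groups, the main values, the gene lists, this rule and most of the alternatives were set before the data were examined. Of the label-check genes, psc3, cdc10, leu1, ade6 and swi6 lie where positions do not match and were not analysed here; clr4 was located by the loss of input signal in clr4d within 5 kb of its reference place. No per-sample columns other than those described were present (0).

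The alternatives were normexp background correction with an offset of 50 (on median signals), loess within arrays, centring on gene probes, scaling to equal median absolute deviation, the authors' value table, filters on dim probes, other widths, probe minimums, peak heights and overlaps. Alternatives without saturated probes, without marked probes, with the Cy5 channel alone, with coding-sequence gene ends and without genes sharing words of 25 bases were added after the data were seen. On simulated data of 342 genes with 40 changed by 1.5 on the log2 scale, the gene step recovered all 40 and called 1 unchanged gene, the peak step recovered 100 of 100 planted peaks, and the position check recovered 3 of 3 planted shifts. The simulated noise was independent from probe to probe, unlike in the arrays, so these numbers check the code and not the error rate here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.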

Results

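Psc3 is a subunit of cohesin, the ring-shaped protein complex that holds sister chromatids together. Its position along the genome of fission yeast, Schizosaccharomyces pombe, was measured by chromatin immunoprecipitation of a GFP-tagged Psc3 followed by hybridisation to a tiling microarray (ChIP-chip). On each array the immunoprecipitated DNA carried the dye Cy5 and the input DNA, from whole-cell extract, carried Cy3. A log2 ratio above 0 therefore marks DNA whose ChIP signal, relative to its input signal, was higher than on the median probe of that array. A low input signal alone can also raise the ratio. The series holds 3 arrays, 1 for each group. Wild-type cells were grown at 30 °C. The clr4d cells lack Clr4, the methyltransferase for lysine 9 of histone H3 on which fission yeast heterochromatin depends. The cdc10-v50 cells carry a temperature-sensitive allele of Cdc10, a transcription factor needed to start S phase, and were moved from 26 °C to 35 °C for 4 h to arrest in G1, so that allele, temperature and cell cycle stage change together.

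There are no replicates, so no difference below has a replicate error or a p-value. Differences are set against the spread between probes (SD) and against 10000 random runs of the same number of consecutive probes on the chromosome arms. Each array gave values at 41551 genome probes. The wild-type array was scanned at 16 bits and read with 1 version of the scanner software, and both mutant arrays at 20 bits with another, so genotype and batch cannot be told apart in either comparison with wild type. The wild-type scan had 2273 probes (5.47%) at the upper limit of the ChIP channel, and the mutant scans had 0. At these probes the wild-type ratio is a lower bound. The median of the 4 probes of the clr4 deletion on chromosome II (array position 457801 to 459000) checks the strain labels: the input signal there was 1496 in wild type, 1335 in cdc10-v50 and 7.49 in clr4d.

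In wild-type cells Psc3 was concentrated in the constitutive heterochromatin of the centromeres, the mating-type region and the chromosome ends. The median log2 ratio was 2.03 over the 3 centromeres (SD between probes 1.21, 270 probes), 1.81 over the outer 50 kb of chromosomes I and II (SD 0.92, 574 probes) and 1.28 over the contig that carries the mating-type region (SD 1.07, 105 probes). All 3 medians lay above every random run of arm probes. The ends of chromosome III, which border the ribosomal DNA repeats, reached 0.68 (SD 0.73). Saturated probes made up 54.9% of the centromere probes, 49.2% of the subtelomere probes and 48.2% of the mating-type contig, so these wild-type medians are minimum values. The array's separate contigs named pNSU, with 129 probes, had a median of 1.52.

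Within each centromere the wild-type signal had 2 shoulders and a gap in the middle. The fission yeast centromere consists of a central core, on which the kinetochore forms, flanked by repeats that are packed as heterochromatin. Over the middle 6 kb of the 3 centromere intervals the wild-type median was -0.27 (SD 1.00, 49 probes), which was below the median probe of the array. The 116 centromere probes whose names end in m, which lie in the flanks, had a wild-type median of 2.22 (SD 0.49), and 101 of them were saturated. Away from the chromosome ends the wild-type ratio fell from 2.29 in the outer 10 kb of chromosomes I and II to 1.02 between 40 and 50 kb and to 0.31 between 90 and 100 kb.

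On the arms Psc3 lay in short peaks. A running mean over 3 probes at 2-fold or more gave 261 wild-type arm peaks with a median length of 2.40 kb and a median height of 1.36. Each of the highest 10 held saturated probes, so their heights are lower bounds and their true order is not known. The highest measured lay on chromosome III at 275401 to 277200 over mae2, which encodes a malate dehydrogenase, with a height of 2.57. Part of the mae2 sequence also occurs in the outer 50 kb of chromosomes I and II, so its signal may come from those copies. Another peak lay on chromosome III at 115201 to 117300 over tam14 and ura4, the latter encoding orotidine 5'-phosphate decarboxylase of uracil synthesis, with a height of 2.46. The mean over this peak was at least 2.06 in wild type but 0.37 in clr4d and 0.12 in cdc10-v50. Peaks of 2.38 and 2.33 lay on chromosome I at 59101 to 62100 and at 1913101 to 1920000. Chromosome II held 5 of the highest 10, with heights from 2.07 at 3481501 to 2.14 at 1883701. A further 1, on chromosome III at 941101 to 947400 with a height of 2.04, covered pog1 and opy1. Genes could be named only on the left arm of chromosome III between 50 and 1000 kb, the part of the array where tile positions matched the reference.

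In cells without Clr4 the ChIP over input ratio of Psc3 was lower than in wild type at each of the heterochromatic regions. Over the pooled centromeres the clr4d ratio was 0.36 (SD 0.54), above 99.7% of random arm runs. Taken alone, the centromeres of chromosomes I, II and III had 0.27, 0.29 and 0.43, above 84.7%, 83.7% and 96.7% of runs. The clr4d ratio was 0.09 (SD 0.53) over the subtelomeres of chromosomes I and II and 0.05 (SD 0.47) over the mating-type contig. The clr4d minus wild type difference was -1.51 at the centromeres (SD 1.25), -1.59 at the subtelomeres (SD 1.05) and -1.63 at the mating-type contig (SD 1.13). Wild type was thus at least 2.84-fold, 3.002-fold and 3.09-fold above clr4d, and each difference lay below all random arm runs. The ends of chromosome III differed by -0.15, inside the range of the random runs, and had a clr4d ratio of 0.52.

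The difference was not equal across each region. At the telomere-proximal 10 kb of chromosomes I and II the difference was -2.18, between 40 and 50 kb it was -1.06 and between 90 and 100 kb it was -0.26. The left and right ends of chromosome I fell by 1.90 and 2.43, and those of chromosome II by 1.01 and 0.91. At the centromeres the difference came from the flanks: it was -1.71 at the probes marked m (SD 0.67) and 0.22 over the middle 6 kb (SD 1.13). Over the 114 centromere probes unsaturated in wild type, which include most of the middle, the difference was -0.13 (SD 1.02), while the unsaturated probes of the subtelomeres differed by -1.06 and those of the mating-type contig by -0.96. Beside the centromeres the highest clr4d windows differed by chromosome. On chromosome I the 2-kb windows from 3752001 and from 3788001 had clr4d ratios of 1.35 (SD 0.36) and 1.51 (SD 0.16). The wild-type ratios were at least 2.22 and 1.79, with 5 and 4 of 7 probes saturated. The highest on either side reached 1.24 and 0.93 on chromosome II and 0.88 on both sides on chromosome III. The input channel also differed between these arrays: the Cy3 signal of clr4d over wild type was higher by 2.96 on the log2 scale at the centromere probes marked m, by 0.55 at the subtelomeres and by 0.55 at the mating-type contig. At probes unsaturated in wild type the Cy3 difference was 0.01 at the subtelomeres, 0.11 at the mating-type contig and -0.80 at the centromeres, and over all probes of the chromosome III ends it was -0.57. At the probes marked m, the subtelomeres and the mating-type contig the measured Cy5 differences were 1.21, -0.87 and -0.86, which are upper limits because of saturation in wild type, so that the sign at the probes marked m is not known. Over unsaturated centromere probes the Cy5 difference was -0.87.

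**Figure D1:**
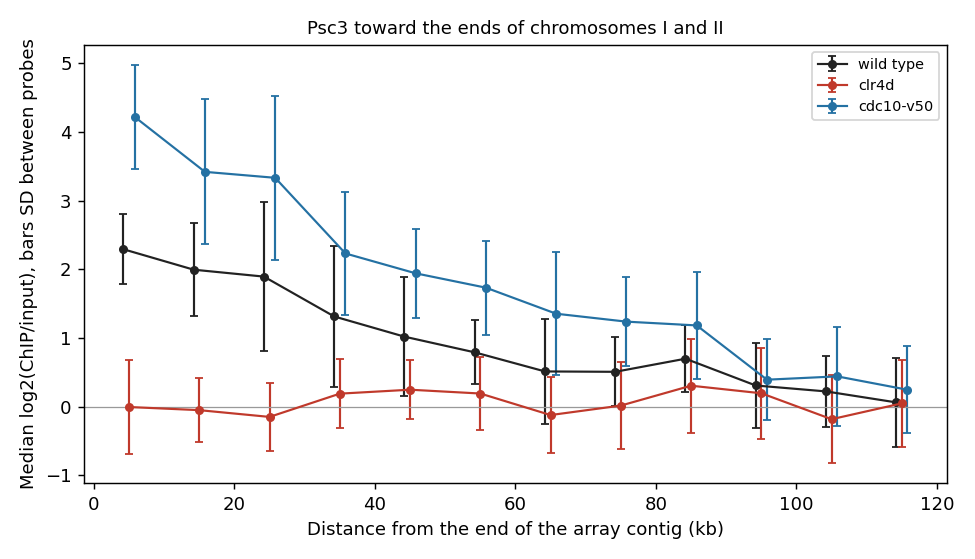
Median log2(ChIP/input) in 10-kb steps from the ends of chromosomes I and II, pooled, for each array; bars are the SD between probes, not between samples. The outermost step stood at 2.29 in wild type, -0.01 in clr4d and 4.22 in cdc10-v50.

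Individual genes on the analysed stretch of chromosome III moved little in clr4d. Of 337 genes with at least 3 probes, 3 were at least 2-fold higher and 5 at least 2-fold lower than in wild type, and the difference between genes had an SD of 0.42. With another background correction (normexp) the counts were 9 and 7. The largest fall was at mae2, from 2.36 in wild type to -0.60 in clr4d, a difference of -2.96 (SD between probes 0.20, 5 probes, all saturated in wild type, hence at least 7.80-fold). Of the 25-base words in the mae2 tiles, 188 of 1776 also occur in the outer 50 kb of chromosomes I and II. ura4 fell by 1.92 (SD 0.30, 4 probes, all saturated in wild type, hence at least 3.79-fold). tpi1, encoding the glycolytic enzyme triosephosphate isomerase, fell by 1.27 (SD 0.31), bpb1, encoding a splicing factor, by 1.21 (SD 0.32), and pmp20, next to ura4, by 1.15 (SD 0.42). pmp20 was outside the naming rule and was chosen after its value was seen. Smaller falls were measured at ctt1, the catalase gene (-0.91), eft202, a gene for translation elongation factor 2 (-0.71), atg1, which encodes the kinase that starts autophagy (-0.66), sfh1, encoding a subunit of the RSC chromatin remodeller (-0.59), pef1, a cyclin-dependent kinase gene (-0.53), and yta4, an ATPase gene (-0.45). The genes with the largest rises were cox19, encoding a copper chaperone of mitochondria (1.23, SD 0.27), mug111 (1.099, SD 0.55) and SPCC1795.12C, of no described function (1.03, SD 0.62). vma21, for assembly of the vacuolar proton pump, rose by 0.95, SPCC1235.17 by 0.85, rsm18, a mitochondrial ribosomal protein gene, by 0.80, pmp31 by 0.77, and rad16, the gene of the DNA repair nuclease XPF, by 0.74. sec59, encoding dolichol kinase, and emc6 had differences of 0.73 and 0.72.

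Across the whole arms, 1 of 2392 windows of 5 kb was at least 2-fold higher in clr4d and 13 were at least 2-fold lower, and 89.3% lay within 0.5 of wild type. The 5 windows that fell most included 3 close to the subtelomeres of chromosome I, at 60001 to 65000 (-1.20), 5505001 to 5510000 (-1.11) and 5520001 to 5525000 (-1.37), and 1 on chromosome II at 2150001 to 2155000 (-1.15), which lies near the mating-type interval. The other, at 1170001 to 1175000 of chromosome III (-1.12, SD 0.44), lies outside the centromere interval, which ends at 1137000. The 310 clr4d arm peaks had a median height of 1.44. Of the 261 wild-type arm peaks 63.2% overlapped a clr4d peak, against 13.4% after random placement on the same chromosome. The ChIP ratios of both arrays had a Pearson correlation of 0.56 across all genome probes and 0.61 across arm probes, where neighbouring probes are not independent.

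In the G1-arrested cdc10-v50 cells Psc3 was enriched at all of the heterochromatic regions. Over probes unsaturated in wild type, the ChIP over input ratio was higher than in wild type at the centromeres and at 3 of the 4 ends of chromosomes I and II. The cdc10-v50 ratio was 4.296 over the centromeres (SD 1.66), 2.65 over the subtelomeres (SD 1.23) and 2.31 over the mating-type contig (SD 1.75). The measured cdc10-v50 minus wild type differences were 2.20 at the centromeres (SD 1.05), 1.06 at the subtelomeres (SD 0.93) and 0.49 at the mating-type contig (SD 0.95). Saturation of the wild-type scan makes these upper limits. Over probes unsaturated in wild type the differences were 1.62 (SD 0.80, 112 probes), 0.87 (SD 0.72) and 0.14 (SD 0.48), the last within its spread. Choosing probes by their wild-type signal favours low wild-type ratios, which can raise these differences. At the subtelomeres the wild-type median was 1.03 over these probes and 1.81 over all. At the 112 centromere probes the Cy5 signal, relative to the arms, differed by -0.71 (SD 1.01) and the Cy3 signal by -2.57 (SD 1.15). The higher ratio there thus came with less input and not with more Cy5 signal. At the subtelomeres the same differences were 1.04 and 0.17. The right end of chromosome I went the other way at its unsaturated probes, with -0.33 (SD 0.93). The left end had 0.96, and the left and right ends of chromosome II had 1.13 and 0.74. Between 45 and 50 kb from the right end of chromosome I cdc10-v50 stood at 2.12 and wild type at 2.63 or more. The ends of chromosome III differed by -0.05 over 50 kb, inside the range of the random runs, but by 0.52 in their outer 20 kb, where most probes of the left end were saturated in wild type.

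The middle of the centromeres, low in wild type, was raised in cdc10-v50. Over the middle 6 kb, where 2 of 49 probes were saturated in wild type, the ratio was 1.94 in cdc10-v50 (SD 0.80) against -0.27 in wild type, a difference of 1.96 (SD 0.82, 48 probes). By centromere it was 1.96 on chromosome I, 1.65 on chromosome II and 2.30 on chromosome III. There the Cy5 signal, relative to the arms, differed by -0.75 between cdc10-v50 and wild type (SD 1.09), and the Cy3 input signal by -2.74 (SD 0.95). At the flank probes marked m the Cy3 signal differed by -0.26, and 101 of the 116 were saturated in wild-type Cy5, so the measured Cy5 difference of 2.94 is an upper limit. At the subtelomeres the Cy5 signal was higher by at most 1.24 and the Cy3 signal by 0.13. Away from the ends of chromosomes I and II, pooled, the ratio between 80 and 90 kb was 1.18 (SD 0.78) in cdc10-v50 and 0.70 (SD 0.49) in wild type, and between 90 and 100 kb the difference was -0.02. The ends were not alike: between 85 and 90 kb cdc10-v50 and wild type stood at 1.56 and 0.79 on the left of chromosome I and 1.97 and 0.72 on the left of chromosome II, but at 0.46 and 0.69 on the right of chromosome I and 0.06 and 0.19 on the right of chromosome II.

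Gene values on chromosome III differed less between cdc10-v50 and wild type than between clr4d and wild type, with an SD between genes of 0.32. There, 1 gene was at least 2-fold higher and 3 at least 2-fold lower, and with normexp the counts were 0 and 7. The higher gene was SPCC794.04C, encoding a transporter (1.02, SD 0.19, 7 probes), which shares 1 word of 25 bases with another place of the reference and is not 2-fold higher after loess normalization. The lower genes were ura4, which fell by 2.26 (SD 0.33, at least 4.79-fold), pmp20, which fell by 1.15 (SD 0.20), and pef1, which fell by 1.05 (SD 0.17). Here too pmp20 was chosen after its value was seen. The other leading rises were at pdh1 (0.72), rpn8, a proteasome subunit gene (0.66), mob2, encoding a kinase activator (0.65), and ago1, encoding the Argonaute protein of the RNA interference pathway (0.59, SD 0.17). bqt3, needed for the meiotic bouquet of telomeres, had a difference of 0.57, mad3, of the spindle checkpoint, 0.55, mug111 0.55, mgl1 0.53 and tap42 0.50. Falls were measured at ade10, of purine synthesis (-0.83), dom34, of ribosome rescue (-0.67), sfh1 (-0.63), eap1 (-0.62), bpb1 (-0.58), duc1 (-0.52), mlo1 (-0.45) and dbl1 (-0.43).

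Of the 2392 arm windows 6 were at least 2-fold higher in cdc10-v50 and 2 at least 2-fold lower, and 95.3% lay within 0.5 of wild type. The largest rises were at 70001 to 75000 of chromosome I (1.43, SD 0.36) and at 115001 to 120000 of chromosome II (1.34, SD 0.38), both toward the left chromosome ends. The largest falls lay at 115001 to 120000 of chromosome III, over ura4 (-1.27), and at 1835001 to 1840000 of chromosome III (-1.07). Of the wild-type arm peaks 69.7% overlapped 1 of the 267 cdc10-v50 arm peaks, against 15.3% after random placement. The correlation with the wild-type array was 0.79 across all probes and 0.78 across arm probes.

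The comparison of the mutants with each other does not use the wild-type array, and both share the scanner depth, the software version and freedom from saturation. The mutants differ in genotype, growth temperature and G1 arrest together. The quality summary marked the cdc10-v50 array for evaluation, and 1215 of its spots were non-uniform, against 9 in clr4d. The ChIP over input ratio was lower in clr4d than in cdc10-v50 at each heterochromatic region: the difference was -4.13 at the centromeres (SD 1.66), -2.62 at the subtelomeres (SD 1.28) and -2.06 at the mating-type contig (SD 1.71), all below every random arm run. The ends of chromosome III differed by -0.23 over 50 kb and by -1.45 in their outer 20 kb. The Cy5 signal alone differed by -1.58 at the centromeres, -2.16 at the subtelomeres and -1.97 at the mating-type contig, and the Cy3 input signal by 2.10, 0.35 and 0.39. At the centromere probes marked m the input of clr4d was higher by 3.28 and the Cy5 signal differed by -1.73. Over the middle 6 kb the ratio differed by -1.72 (SD 0.82), with a Cy5 difference of 0.15 and an input difference of 1.81.

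**Figure D2:**
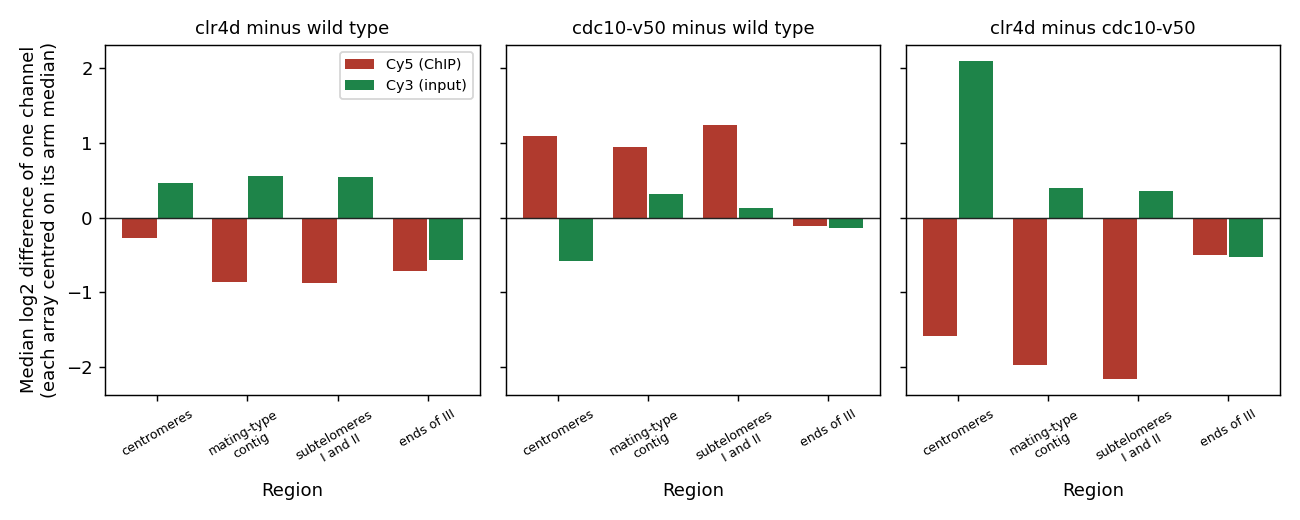
Median log2 difference of the Cy5 (ChIP, red) and Cy3 (input, green) signal, each centred on the arm median of its array, by region and comparison. Subtelomeres and the mating-type contig differ between clr4d and cdc10-v50 mainly in the ChIP channel (-2.16 and -1.97), whereas the centromeres differ in both channels (-1.58 and 2.10); Cy5 differences from wild type are upper limits in the heterochromatic regions.

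On chromosome III no gene was at least 2-fold higher in clr4d than in cdc10-v50 and 1 was at least 2-fold lower, mae2, which fell by 3.82 (SD 0.78). tpi1 differed by -0.85, bpb1 by -0.64, SPCC757.04, a transcription factor gene, by -0.63 and ggc1, encoding a guanine nucleotide transporter, by -0.54. The largest rises were at mug73, a transporter gene (0.85, SD 0.05), vma21 (0.83), cox19 (0.79), SPCC1795.12C (0.77) and mus81, encoding a subunit of a Holliday junction nuclease (0.72, SD 0.66). Of the arm windows 3 were higher and 26 lower at 2-fold, led by 60001 to 65000 of chromosome I (-2.13, SD 0.63). Probe values of the mutants had a correlation of 0.58 genome-wide and of 0.73 on the arms.

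Psc3 was higher between convergent genes than between divergent genes on every array. The analysed stretch of chromosome III held 22 intergenic regions between genes that are transcribed toward each other, 127 between genes of the same direction and 81 between genes that point away from each other. In wild type the class medians were 0.10, -0.23 and -0.63, in clr4d 0.63, 0.02 and -0.32, and in cdc10-v50 0.51, -0.04 and -0.43. Convergent minus divergent was 0.73 in wild type (1.66-fold), 0.94 in clr4d (1.92-fold) and 0.94 in cdc10-v50 (1.92-fold), each above all 10000 shuffles of the class names. The SD between regions of a class ranged from 0.46 to 0.66. When the arrays were first subtracted region by region, convergent minus divergent of the class medians was 0.10 for clr4d minus wild type and 0.04 for cdc10-v50 minus wild type, at percentiles 80.8 and 66.9 of the shuffles.

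**Figure D3:**
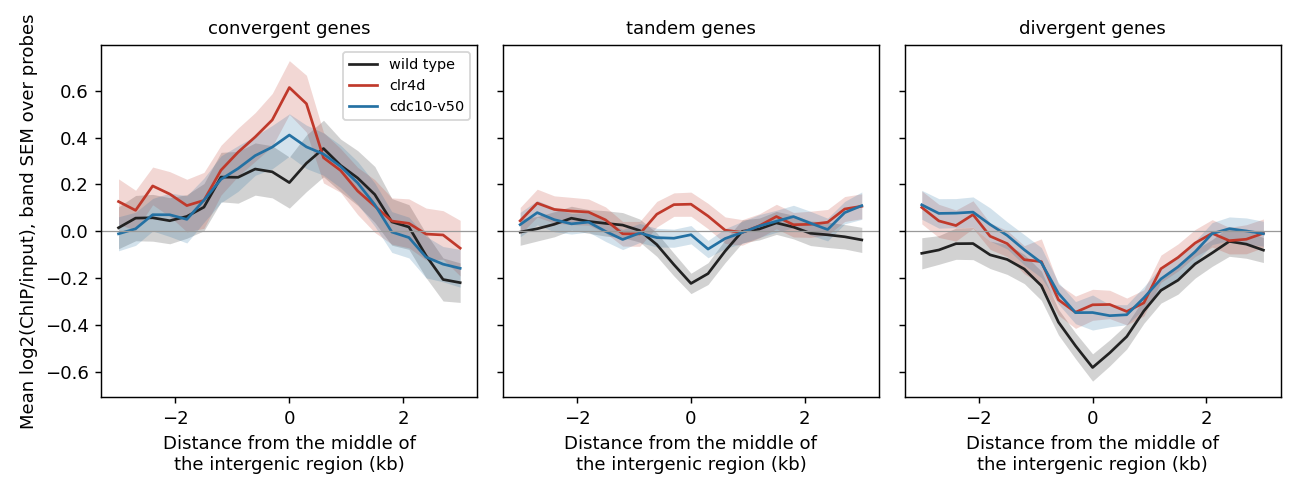
Mean log2(ChIP/input) against distance in kb from the middle of intergenic regions on the left arm of chromosome III, by gene orientation and array; bands are the SEM over probes. At distance 0 convergent regions stood at 0.21 in wild type, 0.61 in clr4d and 0.41 in cdc10-v50, and divergent regions at -0.58, -0.31 and -0.35.

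Transcribed gene groups on the stretch showed no shift as large as that of the heterochromatin. The 11 tRNA genes measured, each with the flanking 500 bp, had medians of -0.05 in wild type (SD between genes 0.52), 0.20 in clr4d and -0.03 in cdc10-v50, and 8 of the 11 were higher in clr4d than in wild type. That share was no larger than among intergenic regions, of which 19 of 22 convergent, 90 of 127 tandem and 59 of 81 divergent ones were higher in clr4d. The 3 genes for 5S ribosomal RNA had medians of 0.08, 0.35 and 0.24, and all 3 were higher in clr4d than in wild type (median 0.22). The Tf2 retrotransposon copy measured there had 0.03, 0.40 and 0.31. Of the ribosomal protein genes 4 could be measured: rpl101 differed by -0.38 in clr4d and -0.26 in cdc10-v50, and rpl1702 by 0.09 and 0.17. The lists of heterochromatin islands, Cdc10 target genes, heat-induced chaperones, histones, cohesin genes and telomere-linked helicases had 0 members on the stretch and were not analysed here, and tpi1 was the 1 glycolytic gene.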

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

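The tests of explanation in this part were chosen only after the results were seen. The Cy3 input channel serves only as the denominator of the reported ratios, and its own signal was raised in clr4d at places where the control array was not. Relative to the arms, the input of clr4d exceeded that of wild type by 1.86 on the log2 scale over the centromere of chromosome III and by 1.07 over the left end of chromosome I, both above the middle 95% of random arm runs. The whole-centromere differences were -0.08 on chromosome I and 0.11 on chromosome II, but the probes marked m rose alike on all 3, by 2.93, 3.05 and 2.97 on chromosomes I, II and III. They number 31, 21 and 64. Probes unsaturated in wild type differed by -0.78, -0.84 and -0.78.

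This bears on the low clr4d ratios at heterochromatin. A raised clr4d input alone does not account for the subtelomeres: the Cy5 difference between clr4d and cdc10-v50, neither of which was saturated, was -2.16 there. At probes unsaturated in wild type the Cy5 difference from wild type was -0.96 in clr4d (SD 0.88) and 1.04 in cdc10-v50 (SD 1.05). Choosing probes by their wild-type Cy5 signal can raise both of these values. Part of the -2.16 may thus lie in cdc10-v50, where allele, arrest and temperature change together. At the centromere probes marked m a raised input may be the larger part, since it differed by 3.28 between clr4d and cdc10-v50 against a Cy5 difference of -1.73. Loss of Psc3 without Clr4 stays a hypothesis for the ChIP-channel difference, because a single array stands for the genotype and the preparation of that array was not tested.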

How the results depend on the processing

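The alternatives without saturated or marked probes, with the Cy5 channel alone and without genes sharing words were chosen only after the results were seen. No paired analysis was possible because each group has 1 array. The alternative that leaves out probes of repeated sequence was not run, since the files hold no probe sequences and 0 tiles share a position. Of 354 alternative values for the comparisons, 308 were rated unchanged, and of 422 for named genes 391 were, with 0 changes of sign among the latter. Log2 values were rated unchanged if they moved by less than their SD between probes, regions or genes. That limit is wide: for cdc10-v50 minus wild type the mating-type contig went from 0.49 to 0.14 without saturated probes (SD 0.95). This was rated unchanged, so the number of unchanged values does not measure precision. Counts of genes and peaks were rated by a fixed fold limit, and percentages of shared peaks by a binomial interval. The 12 region values for centromeres, mating-type contig and subtelomeres kept their sign under normexp, loess, gene centring, scaling, the authors' table, the dim-probe filter and region means. The gene probes used for centring had medians of -0.0308, 0.0043 and 0.0048 in wild type, clr4d and cdc10-v50. The arm medians of these arrays were -0.0229, -0.0036 and -0.0222 after loess, against -0.0271, -0.0114 and -0.0265 in the main values. Signal was well above background at nearly every probe, so saturation and not dimness limits the wild-type values.

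Leaving out probes saturated on the wild-type array gave 0.19 for the wild-type centromeres, -0.13 for clr4d minus wild type and -1.74 for clr4d minus cdc10-v50, and leaving out marked probes gave -0.15, 0.047 and -1.90, so that the wild-type value and its difference from clr4d turned in sign. By construction both remove most of the flanks: 39 of the centromere probes are unmarked, with values like those of the middle. Without marked probes the mating-type contig stood at 2.57 in wild type and -3.9995 for clr4d minus cdc10-v50. With Cy5 alone the centromere differences were at most 1.0995 for cdc10-v50 minus wild type and -1.58 for clr4d minus cdc10-v50, which leaves out the input by construction. In the outer 20 kb, the ends of chromosome III differed by -1.45 between clr4d and cdc10-v50. For the mating-type contig and the ends of chromosome III the cause was not tested.

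Genes at 2-fold for clr4d minus wild type numbered 9 higher with normexp, 1 higher and 2 lower with at least 5 probes, and 3 lower without saturated probes. For cdc10-v50 minus wild type 0 were higher with normexp, loess, gene centring, no saturated probes or no shared words, 2 with equal scaling or probe medians, and 7 were lower with normexp and 0 with at least 5 probes. For clr4d minus cdc10-v50 1 was higher and 2 lower with normexp, and 0 lower without saturated probes or shared words. Fewer genes were tested with 5 probes or without shared words; otherwise the cause was not tested. The 4 ribosomal protein genes gave -0.31 and -0.29 against wild type with loess, for clr4d and cdc10-v50, and -0.11 between the mutants with normexp or probe medians; the cause was not tested.

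Arm peaks numbered 518 in wild type with normexp, 73, 84 and 73 in wild type, clr4d and cdc10-v50 at a height of 1.5, and 8, 14 and 23 at 3 scaled median absolute deviations. The share of wild-type arm peaks found in clr4d was 73.7% with loess, 52.1% at 1.5 and 0% at 3 deviations. The share found in cdc10-v50 was 59.1% with normexp, 79.3% with equal scaling, 46.6% at 1.5 and 37.5% at 3 deviations. Higher thresholds leave fewer peaks by construction; for normexp, loess and scaling the cause was not tested.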

Other observations

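The tests of explanation in this part were chosen only after the results were seen. Mitochondrial DNA, which carries no nuclear cohesin and so shows the floor of the precipitation, had a median ratio of -3.99 in clr4d (SD 0.34, 61 probes) and -3.70 in cdc10-v50 (SD 0.37). In wild type it was at most -1.44, an upper bound, since the input was saturated at all 61 probes. The mating-type interval on the chromosome II sequence had ratios of 0.80 in wild type, 0.02 in clr4d and 0.98 in cdc10-v50. On the left arm of chromosome III 6 of 29 clr4d peak summits lay between convergent genes, which cover 6.76% of the stretch, and 10 between tandem genes, which cover 19.8%. In wild type these were 2 and 0 of 17 and in cdc10-v50 1 and 2 of 18, numbers too small to compare.

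The middle of the centromeres had a higher ratio in cdc10-v50 than in wild type. Arm probes of the same wild-type brightness differed by 0.53. The central probes were dimmer in cdc10-v50 than in wild type, with Cy3 at -5.44 against -2.65 relative to the arms. The match on wild-type brightness therefore cannot tell whether a bias of dim probes on the cdc10-v50 array gives the rise. More Cy5 signal is argued against, with a difference of -0.75 against the arms. A lower input signal in cdc10-v50, at -2.74, is consistent with the rise and is a candidate source of it. Whether G1 arrest, the growth temperature or the DNA preparation lowered that input was not tested, so more Psc3 at the central core in G1 stays an open hypothesis.

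The genes mae2 and ura4 lie on the arm of chromosome III but had wild-type ratios as high as heterochromatin. For mae2, 10.6% of the 25-base words of its tiles occur in the outer 50 kb of chromosomes I and II, so its signal may come from those copies, whereas 26 genes sharing words only elsewhere had a median clr4d minus wild type difference of 0.07 (SD 0.36). The 5 other genes that share words with those ends or with the centromere intervals have at most 8 such words, against 188 in mae2. None of these 5 fell 2-fold in clr4d, with values from -0.10 at urm1 to 1.23 at cox19. For ura4, 0 words were found elsewhere in the reference, so shared reference sequence is argued against. Another ura4 copy placed in heterochromatin of the wild-type strain alone could give the same ratios and was not tested. Extra ura4 input was not seen in wild type: the median input signal of its 4 probes was 809 there, 1311 in clr4d and 937 in cdc10-v50. These signals come from 1 array each and are not centred on the arms, so they do not decide the question.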
